A study of Oryza sativa with 36 samples.

How the data were processed

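Transcript levels were measured in embryo and endosperm of rice seeds after 0, 4, 8, 12, 16 and 24 h of imbibition, with 3 arrays for each tissue and time and 36 arrays in all. Per the labels' protocols, seeds were imbibed in sterile distilled water with air bubbling at 30 °C in darkness, and total RNA was amplified, labelled with biotin and hybridised to Affymetrix rice arrays. The deposited table holds log2 signals for 57381 probe sets, which per the submitters' processing notes were made with GCRMA by the authors. The version of GCRMA is not given in the sources used here. Values were used as deposited. The distributions of the columns were alike within each tissue and differed between tissues, so the arrays of each tissue appear to have been normalised apart, and this limits every comparison of tissues. Low signals lie on the floor that GCRMA leaves, where a change cannot be measured in full.

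Arrays were assigned to 12 groups by the tissue and time in the labels. Embryo replicates are numbered 1, 4 and 5 and endosperm replicates 1, 2 and 3, and the labels do not say that they were separate cultures. The 123 Affymetrix control probe sets and 64 reporter probe sets were left out of the tests, which left 57194 rice probe sets. Gene symbols and identifiers came from the array annotation and from the gene table of assembly GCF_034140825.1 (ASM3414082v1), used for names alone. Of the probe sets tested, 22436 mapped to 1 gene, 95 to several and 34663 to no gene in these tables, and the mapped ones covered 17905 genes, 2453 of them with an informative name. The small number of arrays per group limits precision.

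Linear models were fitted with limma 3.58.1 in R 4.3.3, with a mean for each of the 12 groups and empirical Bayes moderation. The comparisons were endosperm minus embryo at each time and averaged over times, each later time minus 0 h in each tissue, an F test over times in each tissue, and the 24 h change in endosperm minus that in embryo. A probe set was called when its Benjamini-Hochberg adjusted p was below 0.05 and its absolute log2 difference was at least 1, and for the F test when the range of its group means over the times was at least 1. Adjusted p-values in the text are from these fits unless another test is named. Standard errors are those of the moderated fit. Shared changes were compared with the number that independent lists of the same sizes would share. Differences of control probe set means were tested with exact 2-sided permutations of 3 against 3 arrays, for which 0.1 is the smallest p possible.

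Each gene was represented by its brightest probe set. Of 50 gene lists fixed by gene symbol before expression values were examined, 46 with at least 5 genes were tested with camera at its preset correlation of 0.01, again with an estimated correlation, and with fry, in 5 comparisons: tissues at 0 h, tissues at 24 h, each tissue at 24 h against 0 h, and the difference of the 24 h changes. Members were counted as called when adjusted over all probe sets, and also when adjusted over the list alone. Named genes followed a rule set before the data were examined. It took the 5 genes with the largest change in each direction among called genes whose 3 arrays of 1 group lay above all 3 of the other (not required for the difference of changes), up to 3 called members of each list in its majority direction and 1 in the other, and 13 sentinel genes. Genes named outside that rule are said to have been chosen after their values were seen.

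Alternatives set before the data were examined were a replicate block, a harvest day block, moderation with trend and robust fitting, probe sets above the median level only, centring of each array on its 75th percentile or on the hybridisation spike-ins, quantile normalization over all arrays, no minimum fold, arrays of the compared groups only, leaving out each array in turn, replicate 1 of each tissue alone, an estimated correlation, and the mean of all probe sets of a gene. Calls alike under 4 scalings and gene lists after quantile normalization were added after the data had been seen. Other splits of the arrays were counted, all 10 for 3 against 3 and 100 drawn ones elsewhere. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, matplotlib 3.10.9 and jsonlite 2.0.0.

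The procedure was tested on simulated data with the same design and 57194 probe sets, of which 50 were changed at each size. At a log2 change of 0.5, 0 of 50 were called in each comparison, as the fold threshold requires. At 1.5, 50 were called for tissues at 0 h, 50 for tissues at 24 h, 48 for embryo, 49 for endosperm and 42 for the difference of changes. At 2 the numbers were 49, 50, 50, 48 and 50, and at 3 all 50 were called in each. False calls among unchanged probe sets were 0, 0, 3, 1 and 3, and none of the changed ones was called in the wrong direction. The simulated values were independent normal draws around the mean of each probe set over all arrays. They held no other tissue or time effects, no link between replicates and no correlation between probe sets. The false calls therefore do not give the error rate of the real calls.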

Results

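Transcript levels were measured in the embryo and the endosperm of rice seeds (Oryza sativa, cultivar Nipponbare where the labels name one) during the first 24 h of imbibition. Seeds took up water at 30 °C in the dark with air bubbling. The 2 tissues were sampled at 6 times (0, 4, 8, 12, 16 and 24 h, with 0 h the dry seed), which gave 12 groups of 3 Affymetrix rice arrays and 36 arrays in all. Replicates have no order, and the labels do not say that replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical. The arrays of each tissue came from 5 harvest days, which the main fits leave out. The values are log2 GCRMA signals of 57194 rice probe sets, and the small number of arrays per group limits their precision. Values after ± are standard errors of the log2 difference from the fitted model, with n = 3 arrays per group.

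The arrays separated by tissue and by time. The first principal component held 60.7% of the variance and the second held 22.2%, and replicates of a group correlated at Pearson's r of 0.989 to 0.998 across probe sets, which are not independent replicates. Array means lay between 4.11 and 4.18 in embryo and between 3.69 and 3.75 in endosperm, with 95th percentiles of 9.42 to 9.51 and 8.17 to 8.29. The columns of each tissue shared a distribution of their own. The tissues therefore appear to have been normalised apart, and differences between tissues are relative to that. The 3' minus 5' difference of the rice actin, GAPDH and cyclophilin control probe sets was 1.67 (SD 0.42) in embryo and 2.29 (SD 0.26) in endosperm at 0 h, and 1.51 (SD 0.07) and 3.34 (SD 0.14) at 24 h. Mean signal of the rRNA control probe sets was 13.71 (SD 0.12) in embryo and 11.13 (SD 0.21) in endosperm at 0 h, and 8.74 (SD 0.26) and 7.04 (SD 0.27) at 24 h.

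**Figure D1:**
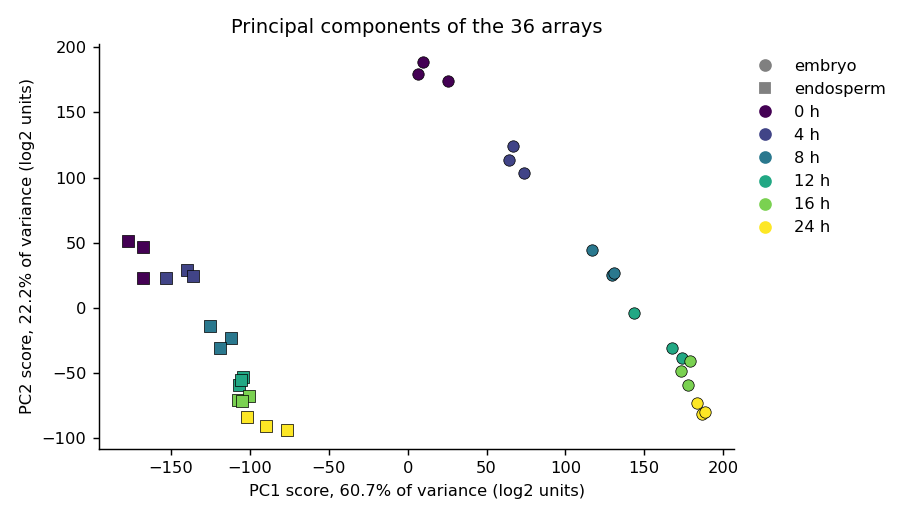
Scores of the 36 arrays on the first and second principal components (x axis, 60.7% of variance; y axis, 22.2%; log2 units), with circles for embryo, squares for endosperm and colour for imbibition time. The tissues lie apart along the first component and both move down the second component with time.

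The first comparison asked which genes differed between the organs in the dry seed, as endosperm minus embryo at 0 h. Of 11 storage protein genes, 9 were higher and 1 lower (median 4.44). The higher genes included the glutelin gene GLUA3 by 5.61 ± 0.39 and the seed allergen genes RAG1 and RA5 by 5.33 ± 0.51 and 5.29 ± 0.46, with 1 of the 2 probe sets of RAG1 not called. The lower gene was GLB (-1.79 ± 0.21), a symbol not known here to stand for the globulin storage protein, which was not called under 75th percentile centring (-0.63) or quantile normalization (-0.41). Cytosolic ribosomal protein genes were lower in endosperm in 28 of 29 cases (median -2.02), and in 13 under 75th percentile centring and under quantile normalization, with 60SP0 at -2.69 ± 0.07 and RPL3 at -2.46 ± 0.08. The KNOX meristem gene OSH1 (-4.87 ± 0.25, adjusted p = 1.65e-15) and the chlorophyll synthesis gene CHLP (-4.49 ± 0.20) were also lower.

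The storage protein list passed camera (adjusted p = 2.51e-07, and adjusted p = 0.228 with an estimated correlation), as did the ribosomal protein list (6.59e-08, and adjusted p = 0.31 with an estimated correlation). Both kept their direction under each scaling of the arrays. Starch synthesis genes divided, with 4 of 8 higher and 4 lower. Wx, the granule-bound starch synthase, was higher by 4.04 ± 0.53 and the branching enzyme gene Sbe1 by 2.59 ± 0.17, while SSII-1 lay at -3.53 ± 0.15. Of the probe sets of Wx and Sbe1, 1 of 6 and 4 of 8 were not called. That list did not pass camera (adjusted p = 0.0851), and its median was 0.34 while fry called it down (adjusted p = 1.98e-04). Among chitinases and pathogenesis-related proteins 4 of 14 were higher and 0 lower (camera adjusted p = 7.71e-05, and adjusted p = 0.217 with an estimated correlation), led by Chib3H-h, a class III chitinase, at 6.34 ± 0.29 (adjusted p = 1.45e-16). The endosperm regulators, 3 genes and so not tested as a list, held 1 higher gene, NFYB1 (2.93 ± 0.19). Of the storage protein proteases, 4 genes, 1 was lower, REP1 (-2.03 ± 0.22), but not under 75th percentile centring (-0.87) or quantile normalization (-0.89). Both pericarp flavonoid genes were lower: CHI at -2.85 ± 0.12, and CHS1 at -1.90 ± 0.23 with 4 of its 5 probe sets not called and no call under 75th percentile centring (-0.73) or quantile normalization (-0.51).

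Several gene groups were lower in endosperm in the deposited values. Under quantile normalization only 3 of the 13 lists called at 0 h kept their call, storage proteins, ribosomal proteins and chitinases, and none of the lists that follow did. ER folding genes were lower in 20 of 27 cases (OST3 -2.61 ± 0.10; camera adjusted p = 0.0352, and adjusted p = 0.416 with an estimated correlation). Of these, 3 were higher and 5 lower under 75th percentile centring. Proteasome subunits were lower in 11 of 14 cases (RPN7 -2.47 ± 0.08; 0.0263, and adjusted p = 0.416 with an estimated correlation). TCA cycle and respiration genes were lower in 17 of 25 with 1 higher (0.0299, and adjusted p = 0.416 with an estimated correlation) and translation factors in 8 of 9 (0.0302, and adjusted p = 0.313 with an estimated correlation). Under 75th percentile centring 1, 1 and 0 genes of these last lists stayed lower, and the proteasome median turned to 0.01 under quantile normalization. AOX1a, the mitochondrial alternative oxidase, was the respiration gene that was higher (1.77 ± 0.19). ABA metabolism and signalling genes were lower in 19 of 24 cases (SAPK7 -4.02 ± 0.27) without a camera call (0.0709), in 7 with 1 higher under 75th percentile centring and in 6 with 2 higher under quantile normalization. Beta-glucosidases, cellulose synthases, jasmonate, nitrogen, phenylpropanoid and sugar transporter genes were called up by camera (adjusted p from 0.00389 to 0.0352, and adjusted p from 0.217 to 0.442 with an estimated correlation), although their medians lay between -0.32 and 0.00 and fry gave down for each. Camera ranks a list against all other genes, most of which were lower in endosperm.

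In all, 14638 probe sets (25.6% of those tested) were called at 0 h, 1357 higher and 13281 lower in endosperm. This balance depended on scaling: 33259 were higher and 3114 lower under 75th percentile centring, which moved the median difference to 1.1. Array medians were alike (2.8 to 2.93 in embryo, 2.72 to 2.81 in endosperm), while 75th percentiles were 5.21 to 5.77 and 4.12 to 4.53. Matching these percentiles raised endosperm probe sets at the floor, so those counts cannot decide the balance. Under quantile normalization, which gives every array the same distribution, 3205 were higher and 3705 lower. Of the main calls, 1356 higher and 2441 lower were called alike under all 4 scalings.

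In the same organ comparison at 24 h the storage genes RAG1 (9.59 ± 0.51, adjusted p = 5.07e-15, 1 of its 2 probe sets not called), RA5 (9.21 ± 0.46), GLUA1 (8.97 ± 0.56) and GLUD1 (8.95 ± 0.51) were far higher in endosperm. The beta-expansin gene EXPB2 (-8.26 ± 0.37, adjusted p = 1.54e-16), the beta-glucosidase gene BGLU12 (-7.53 ± 0.36), the lipoxygenase gene LOX1.1 (-7.31 ± 0.54) and the tubulin gene TUBB8 (-7.13 ± 0.35) were far lower. In endosperm EXPB2 (2.40) and TUBB8 (2.89) lay at the floor, near array medians of 2.73 to 2.75, so their differences are only bounds. RAG1 stood near the array maxima in endosperm at 0 h without a called change by 24 h, so its difference is not exact either. For the first 7 of these genes all 3 arrays of the higher tissue lay above all 3 of the other, which the naming rule required of the largest changes.

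Of the storage protein genes 9 of 11 were again higher and 1 lower (GLB, -1.45 ± 0.21; median 8.36, camera adjusted p = 2.05e-09, and adjusted p = 0.0953 with an estimated correlation). The lower call was lost under 75th percentile centring (10 higher, 0 lower) and quantile normalization (9 higher, 0 lower). Aleurone and scutellum secretion genes held 4 higher and 0 lower of 7 (1.44e-04, and adjusted p = 0.0953 with an estimated correlation). They included the alpha-amylase gene AMY3A at 7.41 ± 0.31, the 1-Cys peroxiredoxin gene R1C-Prx at 2.91 ± 0.22 and the gibberellin-responsive regulator GAMYB at 2.65 ± 0.19. The labels leave open whether the embryo samples held the scutellum. Phytate genes were higher in 6 of 10 cases and lower in 1 (7.43e-05, and adjusted p = 0.0953 with an estimated correlation), with ITPK4 at 2.98 ± 0.22. LEA and dehydrin genes were higher in 5 of 9 and lower in 1 (3.88e-04, and adjusted p = 0.276 with an estimated correlation), with rab25 at 4.98 ± 0.34 and RAB21 at 1.86 ± 0.14. Starch synthesis held 4 higher and 2 lower of 8 (0.00516, and adjusted p = 0.116 with an estimated correlation), with Wx at 7.74 ± 0.53. Under quantile normalization 11 of the 17 lists called at 24 h kept their call, and those of starch synthesis, ER folding, proteasome, chitinase, potassium transporter and reference genes were lost. Fat breakdown and glyoxylate genes held 2 higher and 0 lower of 6 (0.00833, and adjusted p = 0.0953 with an estimated correlation): the peroxygenase gene PXG at 5.09 ± 0.33 and ICL, isocitrate lyase, at 3.24 ± 0.16. These 6 lists kept their direction under each scaling.

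Most genes of several growth and division lists were lower in endosperm at 24 h, in the same direction under each scaling. DNA replication genes were lower in 29 of 32 cases and higher in 0 (camera adjusted p = 9.07e-04, and adjusted p = 0.293 with an estimated correlation). Examples were RPA1B at -4.82 ± 0.27 and MCM3, of the replicative helicase, at -4.09 ± 0.24. Of this list 15 were lower and 1 higher under 75th percentile centring, and 17 were lower under quantile normalization. All 6 histone genes were lower (0.0211, and adjusted p = 0.276 with an estimated correlation). So were 14 of 15 tubulin and actin genes (0.0185, and adjusted p = 0.425 with an estimated correlation) and 21 of 30 expansin and xyloglucan genes (0.0497, and adjusted p = 0.293 with an estimated correlation). For expansin genes 75th percentile centring gave 6 higher and 18 lower. Of 24 cyclins and mitotic kinases 19 were lower and 1 higher without a camera call (0.0573), with CYCB1-1 at -5.49 ± 0.51. The higher gene, CYCD5-2, had 2 probe sets called in opposite directions. Ribosomal proteins were lower in 26 of 29 cases (4.46e-06), proteasome subunits in 13 of 14 (0.0021), ER folding genes in 23 of 27 (0.0106) and translation factors in 7 of 9 (0.0301). Each of these 4 lists had adjusted p = 0.276 with an estimated correlation. Under 75th percentile centring only 1, 2, 5 and 0 genes of these lists were lower.

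The common reference genes were lower in 5 of 8 cases (0.0357, and adjusted p = 0.276 with an estimated correlation), including UBQ5 at -2.12 ± 0.11, which was not called under 75th percentile centring (-0.91). Chitinases held 5 higher and 3 lower of 14 (0.0021, and adjusted p = 0.169 with an estimated correlation), without a call under quantile normalization (0.101). Potassium transporters held 5 higher and 8 lower of 23 and were called up by camera (0.0368, and adjusted p = 0.234 with an estimated correlation) with a median of 0.01, a mean of -0.34 and fry down, and 75th percentile centring gave 14 higher and 3 lower. Of the untested lists, 1 of 3 endosperm regulators was higher (NFYB1, 3.56 ± 0.19) and 1 lower (RSR1, an AP2 regulator of starch synthesis, -3.20 ± 0.31). Among storage proteases AP25 was the 1 lower gene (-4.89 ± 0.26). CHS1 was the 1 lower pericarp gene (-2.18 ± 0.23, 3 of 5 probe sets not called), at -0.97 without a call under 75th percentile centring and quantile normalization. In both organ comparisons every list count named here was the same when adjusted over the list alone.

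At 24 h 14592 probe sets were called, 1707 higher and 12885 lower in endosperm, against 35780 higher and 3800 lower under 75th percentile centring (median difference 1.19), 1464 and 14939 under spike-in centring (-0.23) and 4063 and 4566 under quantile normalization. Calls at the other times were 14599 at 4 h, 14733 at 8 h, 14815 at 12 h and 14971 at 16 h, between 6.71% and 11.0% of them higher. Averaged over the 6 times, 1255 probe sets were higher and 13670 lower. The 3' minus 5' difference of the rice controls was larger in endosperm than in embryo at both ends of the course, as given above, beside every group named in these comparisons.

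The second comparison asked what changed in the embryo from the dry seed to 24 h. All 9 LEA and dehydrin genes fell (median -4.64), with RAB16C falling by 7.52 ± 0.43 and EMP1 by 4.64 ± 0.26 (adjusted p = 2.45e-14), and the heat shock gene hsp101 fell by 7.89 ± 0.31 (2.36e-17). The beta-expansin genes EXPB3 and EXPB2 rose by 8.72 ± 0.26 (1.59e-19) and 8.10 ± 0.37, the beta-glucosidase gene BGLU12 by 8.81 ± 0.36 (6.15e-17) and the lipoxygenase gene LOX1.1 by 8.00 ± 0.54. At 0 h EXPB2 (2.56), BGLU12 (2.19) and EXPB3 (3.09) lay at or near the floor, so these rises are bounds as well. All 3 arrays at 1 time lay above all 3 at the other for the last 4 genes and for hsp101, which the naming rule required of the largest changes.

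Of 24 cyclins and mitotic kinases, 20 rose and 0 fell (camera adjusted p = 1.92e-04, and adjusted p = 0.262 with an estimated correlation). The mitotic cyclin genes CYCB1-1 and CYCB2-2 rose by 7.15 ± 0.51 and 6.62 ± 0.54. DNA replication genes rose in 15 of 32 cases and fell in 3 without a camera call (0.0906). MCM2 rose by 5.77 ± 0.33, and FEN1B, a flap endonuclease, fell by 1.54 ± 0.11 (1 of its 2 probe sets not called). Of cellulose and hemicellulose synthase genes 19 of 29 rose and 1 fell (1.92e-04, and adjusted p = 0.251 with an estimated correlation). So did 18 of 30 expansin and xyloglucan genes with 2 falling (0.00116, and adjusted p = 0.251 with an estimated correlation) and 9 of 17 glucanases and mannanases with 0 falling (0.0263, and adjusted p = 0.262 with an estimated correlation). CSLF6, a mixed-linkage glucan synthase, rose by 6.25 ± 0.22 (2 of 3 probe sets not called), and EXLA1 fell by 4.32 ± 0.21. Tubulins and actins rose in 11 of 15 cases (5.44e-04, and adjusted p = 0.262 with an estimated correlation), TUBB8 by 6.99 ± 0.35. TUBB8 also started near the floor, so its rise is a bound.

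Gibberellin, cytokinin and auxin response factor lists had no camera call in embryo (adjusted p = 0.927, 0.411 and 0.601). Auxin response genes rose in 20 of 35 cases and fell in 3 (0.00252, and adjusted p = 0.251 with an estimated correlation), IAA12 by 7.18 ± 0.28, while IAA4 fell by 3.09 ± 0.23. Jasmonate genes rose in 23 of 36 and fell in 3 (0.00236, and adjusted p = 0.262 with an estimated correlation), with the JAZ-type repressor gene TIFY10B up by 7.75 ± 0.52. ABA genes fell in 13 of 24 cases and rose in 1 (4.17e-04, and adjusted p = 0.251 with an estimated correlation). The phosphatase genes PP2C68 and PP2C51, known as negative regulators of ABA signalling, fell by 5.30 ± 0.39 and fell by 4.43 ± 0.25. SAPK3 fell by 4.46 ± 0.21, while SAPK7 rose by 1.43 ± 0.27. Heat shock transcription factors fell in 13 of 20 and rose in 2 (6.61e-04, and adjusted p = 0.251 with an estimated correlation), HSFA6B by 6.4 ± 0.28. HSFA2C rose by 4.30 ± 0.27 at its brighter probe set and was called in the opposite direction at the other.

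Storage protein genes fell in 9 of 11 cases in embryo (0.0147, and adjusted p = 0.42 with an estimated correlation), and GLUA1 fell by 4.64 ± 0.56. Starch synthesis genes also fell in 5 of 8 cases (median -1.23) without a camera call (0.0732), and Wx fell by 3.57 ± 0.53. Embryo arrays of Wx spread from 6.178 to 8.539 at 12 h and from 4.817 to 7.766 at 16 h. Whether endosperm RNA in the embryo arrays held part of these storage and starch signals was not tested. Phytate genes fell in 8 of 10 and rose in 1 (0.0019, and adjusted p = 0.251 with an estimated correlation), ITPK4 by 5.63 ± 0.22. ER folding genes rose in 13 of 27 and fell in 2 (0.0166, and adjusted p = 0.308 with an estimated correlation), BIP1 by 1.96 ± 0.17. Phenylpropanoid genes rose in 13 of 26 and fell in 1 (0.0166, and adjusted p = 0.262 with an estimated correlation), and chitinases in 10 of 14 with 1 falling (0.0331, and adjusted p = 0.272 with an estimated correlation). Proteasome subunits rose in 4 of 14 (0.0263, and adjusted p = 0.407 with an estimated correlation) and ribosomal proteins in 3 of 29 (0.012, and adjusted p = 0.492 with an estimated correlation), RPL18 by 4.38 ± 0.15. Under 75th percentile and spike-in centring 8 and 16 ER folding, 2 and 7 proteasome and 1 and 11 ribosomal protein genes rose. Photosynthesis genes rose in 11 of 22 and fell in 2 without a camera call (0.0864), the plastocyanin gene PETE by 7.03 ± 0.35. RSR1 rose by 5.76 ± 0.31 as the 1 called endosperm regulator. AP25 rose by 7.75 ± 0.26 and CHS1 by 2.57 ± 0.23 (3 of 5 probe sets not called). VPE1 fell by 1.94 ± 0.10 (2 of 4 not called). No list called in embryo changed direction under a scaling, and all counts were the same when adjusted over the list alone.

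By time, 4071 probe sets rose and 2425 fell at 4 h in embryo, 5471 and 4059 at 8 h, 6070 and 4757 at 12 h, 6466 and 5195 at 16 h, and 6875 and 5778 at 24 h. An F test over all times called 16599. At 24 h, 75th percentile centring gave 5418 up and 7960 down (median difference -0.43), and spike-in centring 9066 up and 3972 down (0.39). The rRNA control signal was 13.71 at 0 h and 8.74 at 24 h beside the ribosomal protein genes named above (exact 2-sided permutation p = 0.1, the smallest that 3 against 3 arrays allow).

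**Figure D2:**
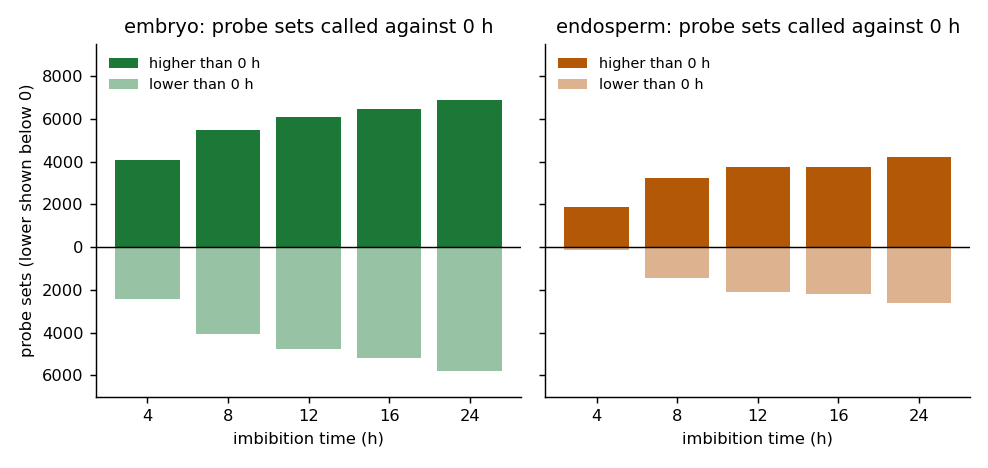
Number of probe sets called higher (above 0) and lower (below 0) than at 0 h (y axis) at each imbibition time in hours (x axis) in embryo (left) and endosperm (right), n = 3 arrays per group. In endosperm 1871 were higher and 149 lower at 4 h, and 4194 and 2612 at 24 h, but 75th percentile centring turned the 24 h balance to 2941 higher and 4268 lower, and that in embryo to 5418 and 7960.

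The third comparison asked what changed in the endosperm over the same 24 h. Ribosomal protein genes rose in 10 of 29 cases and fell in 0 (median 0.82), RACK1B by 1.94 ± 0.10 and RPL18 by 1.86 ± 0.15. Of these genes 5 rose under 75th percentile centring and 17 under spike-in centring. No storage protein gene was called up or down (0 and 0 of 11, median -0.06, camera adjusted p = 0.73). RAG1 stood at 13.31 at 0 h where array maxima in endosperm were 14.3 to 14.5, so a rise of it could not be measured well, though GLB stood at only 5.17. LEA genes fell in 7 of 9 cases, RAB16D by 5.41 ± 0.35 and EMP1 by 3.4 ± 0.26 (adjusted p = 5.01e-11). The genes with the largest rises were CPS4 (6.11 ± 0.55), DTS2 (6.16 ± 0.59, 2.66e-09), CYP99A2 (6 ± 0.69) and OsMAS (5.91 ± 0.68), known for synthesis of the diterpenoid momilactones, and the alpha-amylase gene AMY1A (6.06 ± 1, 1.93e-05). In all 5, each 24 h array lay above each 0 h array, as the naming rule required, but AMY1A was not called when only the arrays of the compared groups entered the fit. For AMY1A the endosperm 24 h against 0 h rise was 4.19 without endosperm 0 h replicate 1 and 7.71 without endosperm 0 h replicate 3. The 0 h endosperm arrays of CPS4, DTS2 and CYP99A2 also spread widely, as the SDs given below show, so the sizes of their rises are uncertain. The largest falls were in small heat shock protein genes, such as HSP23.2 by 5.98 ± 0.60, and in hsp101 by 5.77 ± 0.31.

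The ribosomal list passed camera (1.82e-09, and adjusted p = 0.534 with an estimated correlation), as did LEA (1.73e-04, and adjusted p = 0.538 with an estimated correlation). Heat shock transcription factors fell in 11 of 20 cases and rose in 2 (8.83e-04, and adjusted p = 0.534 with an estimated correlation), HSFA6B by 5.07 ± 0.28, and the 2 probe sets of HSFA2C were again called in opposite directions. Respiration genes rose in 12 of 25 and fell in 2 (8.83e-04, and adjusted p = 0.534 with an estimated correlation). The mitochondrial porin genes VDAC1 and VDAC5 rose by 2.08 ± 0.13 and 2.06 ± 0.13. Glycolysis genes rose in 7 of 17 (0.0393, and adjusted p = 0.538 with an estimated correlation), with the aldolase gene FBA1 up by 4.56 ± 0.57. ABA genes fell in 9 of 24 and rose in 1 (0.0122, and adjusted p = 0.534 with an estimated correlation). SAPK9 fell by 3.1 ± 0.22, and SAPK7 rose by 3.88 ± 0.27. Cellulose synthase genes rose in 12 of 29 (0.0122, and adjusted p = 0.538 with an estimated correlation), CSLF2 by 4.68 ± 0.27. ER folding genes rose in 11 of 27 with 1 falling (0.016, and adjusted p = 0.538 with an estimated correlation). Tubulins and actins rose in 9 of 15 with 1 falling (0.0393, and adjusted p = 0.599 with an estimated correlation) and auxin response factors in 6 of 15 (0.0448, and adjusted p = 0.538 with an estimated correlation). Under 75th percentile and spike-in centring 6 and 14 ER folding genes and 3 and 8 auxin response factors rose. The auxin response factor call was lost under quantile normalization, and with the mean of all probe sets of a gene 7 of the 10 lists stayed called, without auxin response factors, glycolysis and tubulins. None of these called lists changed direction under a scaling.

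Lists without a call in endosperm also held genes that changed. Among aleurone and scutellum secretion genes 3 of 7 rose (camera adjusted p = 0.414): AMY1A, AMY3E (3.9 ± 0.32) and GAMYB (2.25 ± 0.19). The cysteine protease gene REP1 (2.87 ± 0.22) and AP25 (2.96 ± 0.26) rose among the storage proteases, and VPE1 fell by 1.29 ± 0.10 (3 of 4 probe sets not called). SWEET15 and SWEET1B, sugar transporter genes, rose by 4.53 ± 0.40 and 4.23 ± 0.41, the nitrate reductase gene NIA1 by 4.16 ± 0.32 (1 of 2 probe sets not called) and the sucrose synthase gene SUS1 by 4.76 ± 0.36. Fat breakdown and glyoxylate genes had 1 risen and 2 fallen of 6 (camera adjusted p = 0.816), with PEX11-1 falling by 3.51 ± 0.22 and PXG by 1.53 ± 0.33. Starch degradation had 3 risen and 1 fallen of 9 (0.589), and DPE1 fell by 1.07 ± 0.14, not called under spike-in centring (-0.86). Both pericarp flavonoid genes rose (CHI 2.29 ± 0.12; CHS1 2.28 ± 0.23, 4 of 5 probe sets not called), and RSR1 rose by 3.27 ± 0.31 among the endosperm regulators. Counts were the same when adjusted over the list alone.

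Fewer probe sets were called in endosperm than in embryo at each time: 1871 up and 149 down at 4 h, 3222 and 1440 at 8 h, 3724 and 2118 at 12 h, 3757 and 2208 at 16 h, and 4194 and 2612 at 24 h, with 9819 by the F test. Endosperm signals were lower (75th percentiles of 4.12 to 4.53, against 5.21 to 5.77 in embryo), and changes near the floor cannot be measured in full. These counts therefore do not compare the sizes of the responses. At 24 h the split was 2941 up and 4268 down under 75th percentile centring (median difference -0.37) and 5369 and 1949 under spike-in centring (0.18). Beside all these groups the 3' minus 5' difference of the rice controls in endosperm was 2.10 to 2.59 at 0 h and 3.23 to 3.50 at 24 h (exact 2-sided permutation p = 0.1, the smallest possible).

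Sentinel genes, fixed in advance to mark known seed processes, gave single-gene courses. AMY1A rose in both tissues, by 4.95 ± 1 at 8 h in embryo and 4.63 ± 1 in endosperm, and did not differ detectably between them at 24 h (-0.04 ± 1, adjusted p = 0.975). Its 0 h arrays spread from 5.23 to 9.87 in embryo and from 3.59 to 10.64 in endosperm, and its 0 h tissue difference ranged from -1.67 without endosperm 0 h replicate 3 to 1.85 without endosperm 0 h replicate 1. ABA8OX1, which encodes an ABA-degrading hydroxylase, rose at 4 h by 1.86 ± 0.24 in embryo and 1.77 ± 0.24 in endosperm, and its differences from 0 h at 24 h were -0.31 (0.249) and 0.70 (0.0228), neither called. GAMYB rose by 1.82 ± 0.19 at 4 h in embryo, where 24 h was 0.45 above 0 h and not called. VP1, an ABA-response regulator of maturation, fell in embryo by 1.32 ± 0.16, though not under spike-in centring (-0.88), and was 0.53 higher in endosperm, not called. MFT2, a seed-specific PEBP gene, fell by 3.83 ± 0.22 in embryo and 1.42 ± 0.22 in endosperm. PCNA, the replication clamp, rose by 2.62 ± 0.14 in embryo and 1.31 ± 0.14 in endosperm, the latter not called under 75th percentile centring (0.97). RAB21 fell by 2.58 ± 0.14 in embryo, with -0.63 in endosperm not called. OSH1 rose in embryo by 1.47, 1.65 and 1.52 at 8, 12 and 16 h, and 0.74 at 24 h was not called. In endosperm, where its means were low (3.28 to 4.52), OSH1 rose by 1.24 ± 0.25 at 24 h with 1 of 2 probe sets not called, but by only 0.94 and without a call when endosperm 24 h replicate 1 was left out, and by 0.90 under 75th percentile centring. Wx fell by 3.57 ± 0.53 in embryo (4 of 6 probe sets not called) and stood at 0.14 in endosperm, not called. ICL rose by 1.36 ± 0.16 in endosperm with -0.40 in embryo not called. Bright genes lay near the array maxima, where differences could not be measured well: Wx in endosperm (means 13.53 to 13.67), RAB21 at 0 h (14.19 in embryo, 14.10 in endosperm), EMP1 at 0 h (14.06 and 13.47) and AMY1A at 24 h (13.44 and 13.39). AMY3D stood at -0.14 and 0.79 and GLB at 0.53 and 0.88, none of them called.

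**Figure D3:**
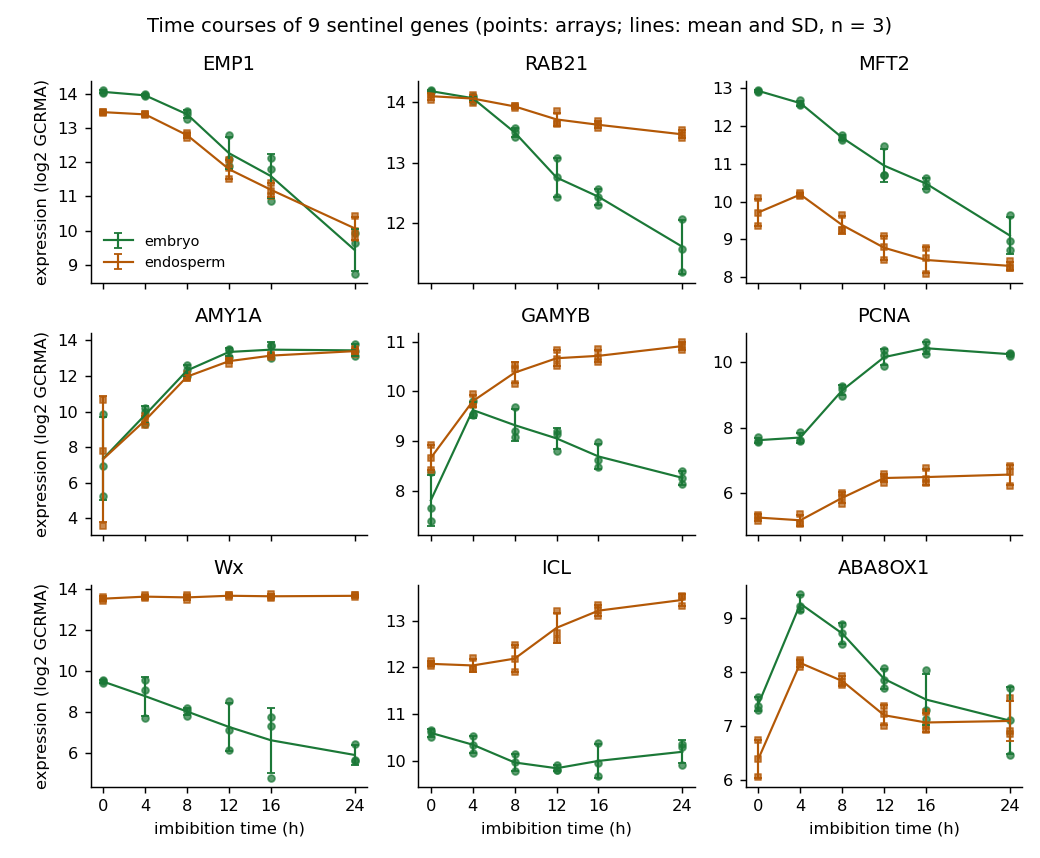
Log2 GCRMA signal (y axis) of 9 sentinel genes against imbibition time in hours (x axis) in embryo (green) and endosperm (orange), with points for arrays, lines for means and bars for SD (n = 3). EMP1 fell in both tissues (by 4.64 and by 3.4 at 24 h), AMY1A rose in both (6.08 and 6.06), and Wx fell by 3.57 in embryo while it stood at 0.14 in endosperm, near the array maximum.

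The fourth comparison asked whether the 24 h change differed between the tissues, as the endosperm change minus the embryo change. Some wall and cell-cycle genes that rose in embryo were lower in the endosperm change: EXPB2 differed by -8.12 ± 0.53 (adjusted p = 4.92e-12), BGLU12 by -8.23 ± 0.51 (2.33e-12), TUBB8 by -6.99 ± 0.50 (2.54e-11) and CYCB1-1 by -5.66 ± 0.72 (5.39e-07). EXPB2 (2.42 at 0 h, 2.40 at 24 h) and TUBB8 (2.89 at both) stayed at the floor in endosperm, so no endosperm change could be measured and their differences rest on the embryo rise. In embryo BGLU12, EXPB2 and TUBB8 started at or near the floor, as said above, so their differences are bounds. Some seed genes that fell in embryo were higher in it: rab25 differed by 5.36 ± 0.49 (1.84e-09), the seed vacuolar aquaporin gene TIP3-1 by 4.82 ± 0.39 (2.89e-10) and GLUA1 by 4.38 ± 0.80 (8.11e-05). AMY3A (4.14 ± 0.44) and AMY3E (3.99 ± 0.45) were also higher in the endosperm change. AMY3E rose in endosperm. AMY3A stood at nearly the same endosperm level at 0 h and 24 h, as given below, so its difference came with a fall in embryo.

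Lists that were lower in the endosperm change were cyclins (17 of 24; 1.32e-06, and adjusted p = 0.18 with an estimated correlation), expansins (16 of 30, 2 higher; 3.45e-05, and adjusted p = 0.137 with an estimated correlation) and cellulose synthases (16 of 29, 1 higher; 2.55e-04, and adjusted p = 0.18 with an estimated correlation). Others were histones (5 of 6; 2.96e-04, and adjusted p = 0.141 with an estimated correlation) and wall glucanases (8 of 17; 0.00121, and adjusted p = 0.137 with an estimated correlation). Jasmonate genes were lower in 19 of 36 cases, 20 when adjusted over the list alone, and higher in 1 (2.64e-04, and adjusted p = 0.199 with an estimated correlation). Auxin response genes were lower in 14 of 35 with 1 higher (9.86e-04, and adjusted p = 0.179 with an estimated correlation). Tubulins were lower in 9 of 15 with 1 higher (9.86e-04, and adjusted p = 0.306 with an estimated correlation) and DNA replication genes in 14 of 32 with 2 higher (0.00815, and adjusted p = 0.372 with an estimated correlation). Aquaporins were lower in 10 of 25 with 4 higher (0.0381, and adjusted p = 0.372 with an estimated correlation) and photosynthesis genes in 8 of 22, 9 when adjusted over the list alone, with 3 higher (0.0439, and adjusted p = 0.372 with an estimated correlation).

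Lists that were higher in the endosperm change were storage proteins (9 of 11; 0.00815, and adjusted p = 0.372 with an estimated correlation), LEA (7 of 9; 0.0111, and adjusted p = 0.408 with an estimated correlation) and phytate (6 of 10; 0.001, and adjusted p = 0.179 with an estimated correlation). Others were ABA (13 of 24; 0.00815, and adjusted p = 0.216 with an estimated correlation) and fat breakdown (4 of 6; 0.00815, and adjusted p = 0.137 with an estimated correlation). Aleurone secretion (4 of 7; 0.0125, and adjusted p = 0.187 with an estimated correlation) and starch degradation (4 of 9; 0.0439, and adjusted p = 0.216 with an estimated correlation) were also higher. The starch degradation call was lost with the replicate block. Antioxidant genes were higher in 8 of 31 with 2 lower (0.00961, and adjusted p = 0.25 with an estimated correlation) and heat shock factors in 7 of 20 with 1 lower (0.0381, and adjusted p = 0.372 with an estimated correlation), a call lost under quantile normalization (0.107). Ribosomal proteins were called up by camera (9.86e-04, and adjusted p = 0.372 with an estimated correlation) with a median of 0.39, although the only called member, RPL18, was lower (-2.52 ± 0.22). None of the called lists changed direction under a scaling, and apart from jasmonate and photosynthesis their counts were the same when adjusted over the list alone. The storage protein difference came with falls in embryo, as no such gene was called in endosperm. Among the untested lists RSR1 (-2.49 ± 0.44) and AP25 (-4.80 ± 0.37) were lower and REP1 (2.05 ± 0.32) and CHI (2.32 ± 0.18) higher.

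**Figure D4:**
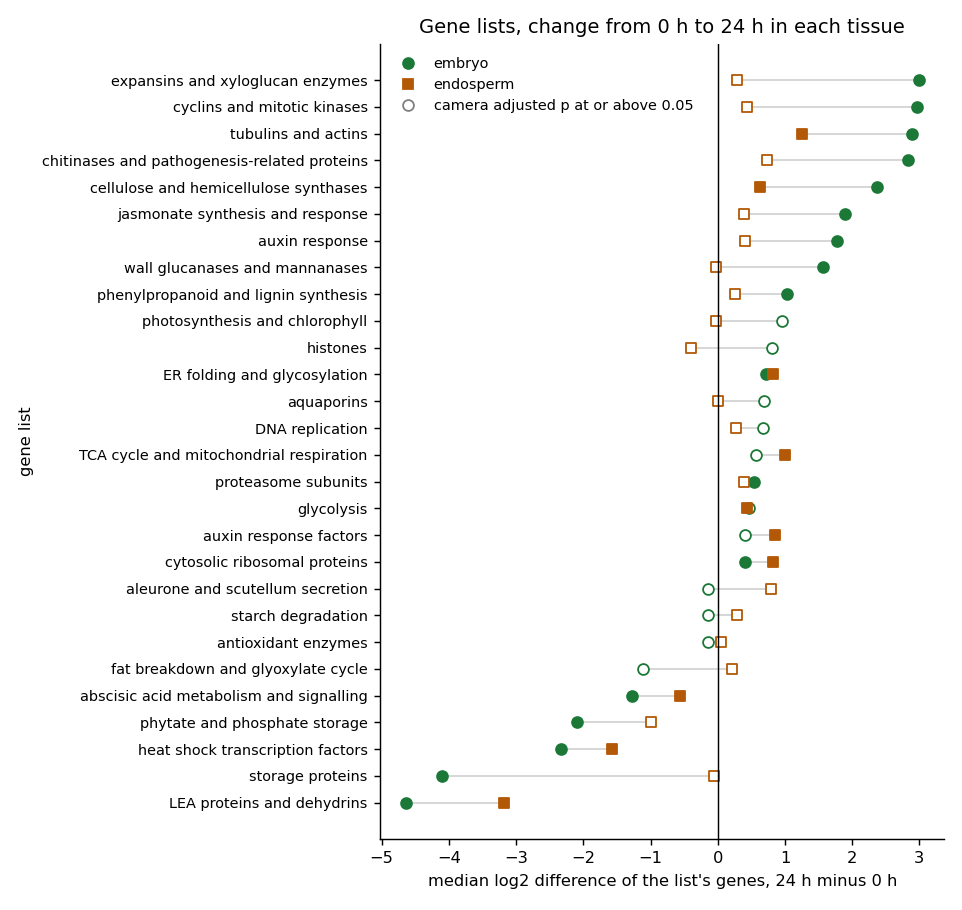
Median log2 difference of the genes of each list, 24 h minus 0 h (x axis), for lists called in at least 1 tissue or in the difference of changes (y axis), in embryo (circles) and endosperm (squares), filled where camera with its preset correlation passed and open where it did not. Storage proteins lie at -4.11 in embryo and -0.06 in endosperm, and cyclins at 2.96 and 0.44. The open medians near 0 change sign under some scalings, such as expansins in endosperm under 75th percentile centring (-0.05), and no filled one does.

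The difference of changes was called for 8797 probe sets, 4400 higher and 4397 lower in endosperm, and spike-in centring gave 2223 and 4483 (median difference -0.22). Of the higher ones, 2174 had fallen in embryo without a call in endosperm and 1021 had fallen in both. Of the lower ones, 2945 had risen in embryo without a call in endosperm and 1088 had risen in both. Changes were nevertheless shared: 3073 probe sets rose in both tissues, where 504.1 would be shared by independent lists, and 2235 fell in both against 263.9. Under 75th percentile centring 2096 rose in both against 278.6 and 3572 fell in both against 594. The tissues share no arrays. Across probe sets the 24 h changes of the tissues correlated at Pearson's r = 0.716 and Spearman's rho = 0.652, and probe sets are not independent replicates.

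**Figure D5:**
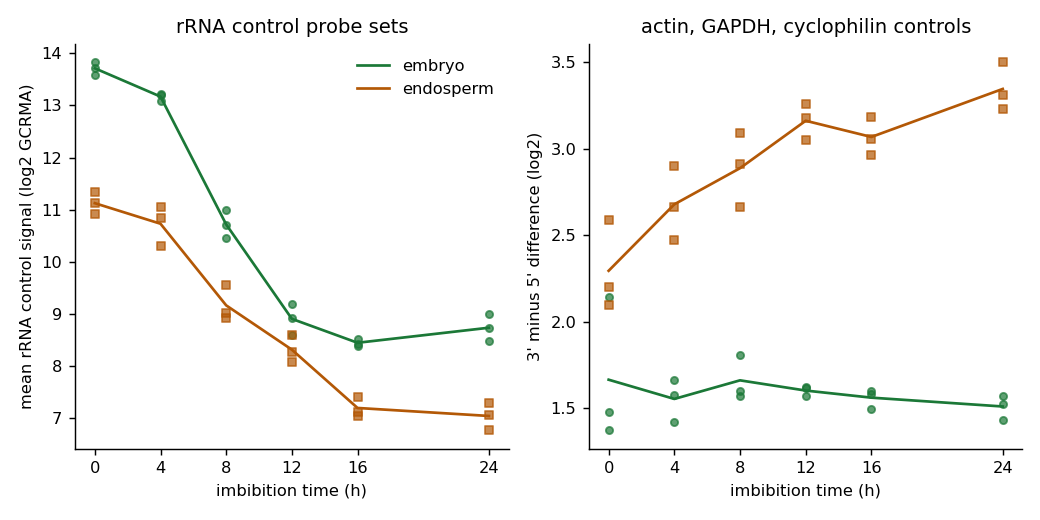
Mean log2 signal of the rRNA control probe sets (left, y axis) and the 3' minus 5' log2 difference of the actin, GAPDH and cyclophilin controls (right, y axis) per array against imbibition time in hours (x axis), with lines for group means in embryo (green) and endosperm (orange). The 3' minus 5' difference averaged 2.29 in endosperm at 0 h and 3.34 at 24 h, against 1.67 and 1.51 in embryo.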

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

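Of the tests in this part, the splits after removal of the additive parts, the comparison with the spike-in transcripts and the choice of the genes with opposite changes came after the results had been seen. The first result stands here because the effect differed between the tissues: the 24 h change differed for 8797 probe sets, among them the beta-expansin gene EXPB2 (LOC4349348, -8.12, adjusted p = 4.92e-12, at the floor in endosperm) and the LEA gene rab25 (LOC4326935, 5.36, 1.84e-09). Of 100 splits of the 12 arrays, 10 gave as many calls, the real one included, and the highest of the others gave 14192. Those splits moved arrays between 0 h and 24 h within each tissue. They left the time changes in the values, so they cannot decide whether chance gave the count. After the additive tissue and time parts were removed, 1 of 100 splits, the real one, gave as many, and the highest of the others gave 5603. This argues against a random grouping of the remaining values. Replicates may be technical, so chance stays open for this count.

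A second difference between the tissues was in direction: 22 probe sets rose in embryo and fell in endosperm by 24 h, where 314 would be shared by independent lists, and 35 fell in embryo and rose in endosperm, against 423.7. The metallothionein gene MT1B rose by 3.77 ± 0.26 in embryo and fell by 1.32 ± 0.26 in endosperm (difference -5.10, adjusted p = 4.39e-11), and DRR1 rose by 2.93 ± 0.19 and fell by 1.51 ± 0.19 (-4.44, 1.5e-12). In the other direction CFBP1 fell by 2.31 ± 0.33 in embryo and rose by 1.85 ± 0.33 in endosperm (4.15, 6.63e-08), and NLP2 fell by 2.30 ± 0.18 and rose by 1.27 ± 0.18 (3.56, 3.16e-11). Centring on the 75th percentile lowers all endosperm 24 h changes alike (median -0.37 against -0.03), which takes the NLP2 rise below the fold threshold.

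Another result lies in control probe sets that the comparisons do not use. The 3' minus 5' difference of the rice controls averaged 3.34 in endosperm at 24 h, above every endosperm array at 0 h (2.10 to 2.59), and higher in 3 of 3 arrays (exact 2-sided permutation p = 0.1, the smallest possible). Scaling of the arrays is argued against, since under quantile scaling the widening of the mean was 1.23, against 1.05 in the deposited values. The labelling reaction may be part of the cause: dap and thr, those of the 4 poly-A spikes with a difference above 1 at 0 h, widened by 0.663 of the rice widening (medians 0.74 and 1.11), and their arrays did not overlap (2.23 to 2.62 at 0 h, 2.67 to 4.37 at 24 h). The other spikes did not follow: lys averaged 0.07 at 0 h and -0.05 at 24 h, and phe -0.02 and 0.20. In embryo the median of dap and thr widened by 0.30 and that of the rice controls by 0.05, with overlapping arrays (2.45 to 6.09 for dap and thr at 0 h, 2.56 to 2.86 at 24 h). The embryo means narrowed instead from 0 h to 24 h: dap from 3.65 to 2.75, thr from 3.71 to 2.73 and the rice controls from 1.67 to 1.51. The embryo arrays therefore give no clear direction. A change in the integrity of endosperm RNA with imbibition stays open as well and was not tested.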

How the results depend on the processing

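Calls alike under 4 scalings and gene lists after quantile normalization were chosen after seeing the data, and unless said otherwise the cause was not tested. Of 376 counts of probe sets under the alternatives, 332 were within 1.5 times the main count and 44 moved further. Under 75th percentile centring the tissue difference was called for 36373, 38032, 38798, 39380, 39886 and 39580 probe sets at 0, 4, 8, 12, 16 and 24 h and 37598 on average, and under quantile normalization for 6910, 5775, 7015, 7735, 8350 and 8629, and 6945 on average. Without a minimum fold, which gives larger counts by construction, these were 39314, 39518, 38992, 39093, 40379 and 39659, and 48767 on average. Likewise embryo at 4 to 24 h gave 28441, 36295, 30702, 41097 and 39082 with 36170 by the F test. Endosperm gave 8464, 21773, 16788, 20118 and 21828 with 19779 by the F test, and the difference of changes 16025. Called alike under 4 scalings, stricter by construction, were 3797, 3056, 4062, 4078, 4865 and 5252 for tissues and 3607 on average, 3929 for embryo at 4 h, 3061 for endosperm at 8 h and 5554 for the difference of changes. Probe sets that fell in both tissues were 3572 and those with opposite changes 91 under 75th percentile centring, and without a minimum fold 6211 rose in both, 9526 fell in both and 947 were opposite. With an estimated correlation 0 gene lists were called for tissues at 0 h, 0 for tissues at 24 h, 0 in embryo, 0 in endosperm and 0 for the difference of changes, against 13, 17, 17, 10 and 21, and quantile normalization left 3 for tissues at 0 h. Of 859 named gene results, 152 lost or gained a call or changed sign under a scaling and 33 did so without 1 array. For tissues at 0 h the reversed values under 75th percentile centring were RAB16C 0.01, HSP81-1 0.01, H2B.11 0.11, ITPK1 0.15, RAB21 1.08 and ABA8OX1 0.15, and under quantile normalization H2B.11 0.07, HXK2 0.02, ITPK1 0.28, VP1 1.01 and ABA8OX1 0.31. At 24 h they were HSFA1 0.16 and ABA8OX1 1.21 under 75th percentile centring, and HSFA1 0.15 and ABA8OX1 1.28 under quantile normalization. Leaving out 1 array gave AMY1A at 0 h from -1.67 to 1.85, and gave 14332 to 15000 probe sets for tissues at 0 h, 1853 to 2225 for endosperm at 4 h and 8575 to 8972 for the difference of changes.

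The replicate numbers were not used to pair the arrays in the main fits. Residuals of arrays with the same number correlated above 0.1 in 23 of 45 pairs in embryo and 12 of 45 in endosperm. Pairs with different numbers did so in 5 and 13 of 90. Arrays of the same number were thus linked, more clearly in embryo: 16 of 18 embryo and 13 of 18 endosperm arrays correlated best with their own number. The main fits leave this link out. With the replicate block 14643 probe sets were called for tissues at 0 h and 3077 rose in both tissues, while the starch degradation list lost its call for the difference of changes, which left 20 of 21. With the harvest day block 14793 were called for tissues at 0 h and 9281 for the difference of changes, and 9 named gene results lost their call. With replicate 1 of each tissue alone, harvested on the same days, and time as a term, 14546 were called for the average tissue difference. Signal over background limits what can be seen for genes near the floor: EXPB2 averaged 2.40 in endosperm at 24 h, where a fall could not be measured.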

Other observations

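Tests in this part chosen after the results had been seen were the count of probe sets near the bound for embryo RNA, the centring on spike-ins and the genes of the first 2 paragraphs. The highest mean of the next genes was at 4 h in both tissues. PDC1 (LOC4339066), a pyruvate decarboxylase gene, averaged 6.13 (SD 0.58) at 0 h, 13.15 (SD 0.14) at 4 h and 11.35 (SD 0.64) at 24 h in embryo, and 6.32 (SD 1.90), 11.64 (SD 0.15) and 10.70 (SD 0.39) in endosperm, with n = 3 arrays each. OsOPR4 (LOC4340486), of the 12-oxophytodienoate reductase family, averaged 5.96 (SD 0.34), 11.65 (SD 0.25) and 8.13 (SD 0.52) in embryo and 4.10 (SD 0.86), 9.32 (SD 0.25) and 6.63 (SD 0.38) in endosperm.

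The momilactone gene DTS2 (LOC4335094) in endosperm averaged 4.06 (SD 1.75), 3.29 (SD 0.24), 5.65 (SD 1.48), 8.58 (SD 0.36), 9.50 (SD 0.33) and 10.22 (SD 0.11) at 0, 4, 8, 12, 16 and 24 h, and 2.99 (SD 0.30) at 0 h and 6.24 (SD 0.37) at 24 h in embryo. CPS4 (LOC4335090) averaged 3.73 (SD 1.22) at 0 h and 9.84 (SD 0.26) at 24 h in endosperm, and CYP99A2 (LOC4335096) 5.26 (SD 1.85) and 11.27 (SD 0.15). AMY3A (LOC4347262) in endosperm averaged 9.79 (SD 0.24) at 0 h, 6.52 (SD 0.69) at 16 h and 9.70 (SD 0.29) at 24 h.

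The tissues shared many changes at 24 h, 3073 probe sets up and 2235 down. RNA like that of the embryo samples, carried into the endosperm arrays, is argued against for most of those that rose in both. Their median endosperm minus embryo level at 24 h was -1.79, while the bound from the lowest 10% of the 100 brightest embryo probe sets was -4.75. Of the 3073, 2753 lay more than 1 above that bound. The other 320 lay no more than 1 above the bound, a margin too small to decide, and cannot be told apart from such RNA, though the lowest of the 100 brightest lay at -8.19. For the 2235 that fell in both, embryo RNA was not tested. The labels leave open whether the embryo samples held the scutellum, so the bound may not cover scutellum RNA. Scaling of the arrays is argued against for those that rose, as the lowest ratio to the number of independent lists over 4 scalings was 4.99. That ratio is likely too high, since the number of independent lists counts probe sets at the floor too. A germination programme common to both tissues stays open and was not tested.

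More probe sets were lower than higher in endosperm. A shift common to all intensities from normalising the tissues apart is argued against, since 93.4% of calls were lower with arrays centred on the hybridisation spike-ins, whose means were 10.10 in embryo and 10.25 in endosperm. The spike-ins are few and bright. Centring on the 75th percentile, which moved the median difference to 1.1 at 0 h and 1.19 at 24 h, turned the balance to 33259 higher and 3114 lower, and 35780 and 3800, and quantile normalization gave 47.1% higher calls at 24 h. The counts therefore depend on the scaling. Centring on the 75th percentile raised endosperm probe sets at the floor, and quantile normalization gives every array the same distribution. Neither can decide the balance, and effects at low intensities stay open. For a few genes taking most of the signal, the 100 brightest probe sets held 7.9 to 8.2 points more in endosperm, under the bound of 10 points set for it. Their share was 20.9% in endosperm against 13% in embryo at 0 h, and 19.9% against 12% at 24 h. The bound was set by choice, so this explanation stays open. A larger range of transcripts in embryo may contribute and was not tested.

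With 3 against 3 arrays there are 10 splits, too few for a share under 0.05, and 1 of 10, the real one, gave as many calls in each such comparison. For tissues at 0, 4, 8, 12, 16 and 24 h the real counts were 14638, 14599, 14733, 14815, 14971 and 14592 and the highest of the others 664, 5, 0, 6, 0 and 2. In embryo at 4, 8, 12, 16 and 24 h the real counts were 6496, 9530, 10827, 11661 and 12653 and the highest others 144, 9, 443, 59 and 16, and in endosperm 2020, 4662, 5842, 5965 and 6806 against 18, 52, 1, 6 and 2. Among 100 drawn splits, 1, the real one, gave as many for the averaged tissue difference (14925, highest other 4237). The same held for the embryo F test (16599, 11402) and the endosperm F test (9819, 6153). This argues against a random grouping of these arrays for these counts, though replicates may be technical. Mean rRNA control signal differed between 24 h and 0 h by -4.98 in embryo and by -4.08 in endosperm, lower in 3 of 3 arrays each (exact 2-sided permutation p = 0.1, the smallest possible).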
